A study of Mus musculus with 48 samples.

How the data were processed

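Metabolically labelled RNA was analysed in 48 libraries of mouse E14 embryonic stem cells, in 16 groups of 3. Groups were taken from the sample titles, which give the line, the hours of dTAG-13 and, except for the SETD2-dTAG line, a batch. The batch of the SETD2-dTAG libraries was not given in the sources used here. Per the labels' protocols, RNA was alkylated with iodoacetamide after addition of ERCC Mix 1 spike-in RNA and made into 3' end libraries from polyadenylated RNA with the QuantSeq FWD kit. No molecular identifiers are stated, so every interval given covers counting error only. Labels number the libraries of a group as biological replicates without saying whether separate cultures were used, so p-values measure only the spread between these samples.

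The authors deposited 1 table per library with the columns and name of slamdunk output, a program that counts T>C conversions, and with 1 line per gene. Read counts, counts of reads with a T>C conversion, counts of covered T positions and counts of conversions are whole numbers, per the file headers and the values. The deposited CPM column has all reads of the table, spike-ins included, as its total. The deposited conversion rate is a fraction, T>C conversions over covered T positions of the gene. The submitters' processing notes name bcl2fastq 2.20.0.422, bedtools 2.27.1, DESeq2 1.30.0 and the builds GRCm38.p6 and mm10, with no role for any of them. The slamdunk version, the mapping settings, the treatment of reads that map to several places and the annotation release were not given in the sources used here. CPM and conversion rates recomputed from the counts matched the deposited columns to rounding in every library. The tests used the counts.

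Tables of the NSD1-dTAG line and its rescue lines had 30878 lines and those of the SETD2-dTAG line 29465, with 29453 identifiers in both. Of 29361 genes in both, 26587 had the same counted length, so a gene's counts were compared within a line, and between these lines only as changes against each line's own 0 h libraries. The tables held 92 spike-ins, which stayed out of library sizes and tests, and 416 lines that join several genes. Of 30382 gene lines, 29697 took their symbol from the GENCODE annotation of GRCm38 by versioned identifier and 618 by identifier without version, and 67 had no symbol. Coordinates are from that annotation (mm10) and give the whole gene.

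Labelled reads, those with at least 1 T>C conversion, were the main measure, and all reads were the other. Differential tests used edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr on the groups, TMM factors from the counts tested, robust dispersions, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment and a threshold of 0.05. Because TMM was set on labelled counts, fold changes are relative to the bulk of genes and an overall change in labelling is removed. Fits held the libraries of 1 batch, or of the SETD2-dTAG line, with 1 mean per group. Differences between lines were interaction contrasts over both lines' libraries. The share of labelled reads was compared by a two-sided exact permutation test of 3 against 3 libraries, whose smallest possible p is 0.1, adjusted over 9 comparisons. From the mean number of conversions per labelled read and the number of T positions per read, a truncated binomial model gave an estimated conversion rate per T of new RNA and an estimated share of new reads. The conversions of each library's spike-in reads were first removed as background. Such estimates rest on the assumption of 1 conversion rate for all new reads and of no background beyond that of spike-ins.

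There were 29 gene lists, tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists with at least 5 tested members. They covered core pluripotency factors with super-enhancers, naive pluripotency, formative and primed pluripotency, primitive endoderm, primitive streak and mesoderm, neural genes, trophoblast, the 2-cell-like state, germline genes under DNA methylation, bivalent developmental regulators, imprinted genes, fibroblast and extracellular matrix genes, and targets of Wnt/beta-catenin, FGF/ERK, LIF/STAT3, BMP and TGF-beta/Nodal. They also covered immediate early genes, p53 targets, the interferon response, heat shock, the integrated stress and unfolded protein response, hypoxia and glycolysis, cholesterol biosynthesis, ribosomal proteins, nucleolar and ribosome biogenesis factors, cell cycle and replication, PRC1 and PRC2 subunits, H3K36 methyltransferases, demethylases and readers, and pause release and elongation. Genes called at 6 h in the NSD1-dTAG line were tested as sets in the comparisons with other 0 h libraries.

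The groups, tests, lists and the rule for naming genes were fixed before the data were examined. The rule names Nsd1 and Setd2, then the 6 largest changes each way among called genes with a mean of at least 10 labelled reads and every treated library on 1 side of every control, then up to 4 called members of each list that passed and up to 2 of any other list, and for interactions the 4 largest each way. Genes without a given name were counted and not named, and some genes that the rule names are not reported here. Others are said to have been chosen after their values were seen.

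None of the 48 pairs of libraries within a group held identical values. Chi-square per gene was 2.28 to 12.8 for labelled reads, highest at 0 h in batch 2 (NSD1-dTAG). For all reads it was 3.05 to 102, highest at 1 h in that batch. No pair lay within sampling noise, and all 3 libraries of each group were kept. Total reads per library were 11646132 to 23335764 and labelled reads 816734 to 2323761. On simulated counts made from the means and library sizes of these libraries, with 100 genes changed per fold size, the test of labelled reads recovered 49% of genes changed 2-fold and 14% of those changed 1.5-fold at 6 h in the NSD1-dTAG line among 9694 genes. At 1 h in the same line 25% and 2% were recovered among 8719 genes. For all reads the shares at 6 h were 70% and 47% among 13106 genes. The model of conversions was tested on 200000 simulated reads, where a true rate of 3% was estimated as 3.09%.

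Alternatives fixed before the data were examined were DESeq2 1.42.0, library sizes from all reads, other filters, fits of only the groups compared and of all 48 libraries, the replicate number as a block, and each library left out in turn. Those chosen after seeing the data were library sizes from ERCC reads, removal of each library's trend on the 0 h labelled share or on T content, genes of equal counted length only, list tests on all reads, and omission of a rescue library whose spike-in share stood apart. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the shares and plots. Read alignments were not analysed here.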

Results

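SLAM-seq measured newly made RNA in mouse E14 embryonic stem cells kept in 2i/LIF, a medium with inhibitors of MEK and GSK3 and the cytokine LIF. In this assay cells take up the nucleoside 4sU for 2 h at 100 µM, and alkylation makes the incorporated base read as C, so that reads of new RNA carry T>C conversions. Proteins were degraded with dTAG-13 at 500 nM, a small molecule that recruits a ubiquitin ligase to a protein carrying the degron tag. The tag was on NSD1, the histone H3K36 methyltransferase mutated in Sotos syndrome, or on SETD2, the enzyme that makes H3K36 trimethylation in transcribed genes. Rescue lines expressed either wild-type full-length NSD1 or the catalytically dead N1751Q form in the NSD1-dTAG background. The names of the deposited tables carry a tag for each rescue line that differs between batches 3 and 4, and its meaning, such as a separate clone, was not given in the sources used here. The NSD1-dTAG line was sampled at 0, 6 and 24 h of dTAG-13 (batch 1) and at 0 and 1 h (batch 2). Rescue lines were sampled at 0 and 6 h (batch 3) and at 0 and 1 h (batch 4), and the SETD2-dTAG line at 0, 6 and 24 h. Hours of dTAG-13 exclude the labelling time, during which the compound stayed on, and 0 h libraries had 4sU alone. Each of the 16 groups had 3 libraries, and every mean below is over 3. Libraries held 11646132 to 23335764 reads (median 17397500), of which 816734 to 2323761 were labelled, and 10509 to 12916 genes had a labelled read. The 10 most abundant genes took 3.44% to 5.0% of labelled reads.

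Treatment with dTAG-13 came with weaker labelling in nearly every comparison. At 6 h in the NSD1-dTAG line the labelled share of reads was 6.83% ± 0.0280 (SD, n = 3) against 11.6% ± 0.0182 at 0 h, and at 24 h it was 8.56% ± 0.284. At 1 h it was 6.29% ± 0.163 against 8.88% ± 0.452. With wild-type NSD1 present the share was also lower, 6.20% ± 0.319 against 7.72% ± 0.35 at 6 h and 6.26% ± 0.159 against 7.55% ± 0.0859 at 1 h. The N1751Q line had 7.71% ± 0.401 against 8.96% ± 0.617 at 6 h and 5.96% ± 0.204 against 7.61% ± 0.167 at 1 h. SETD2-dTAG cells had 8.68% ± 0.182 against 9.57% ± 0.112 at 6 h but 9.99% ± 0.317 at 24 h. All treated libraries lay below all controls in 8 of the 9 comparisons and above them in 1, SETD2-dTAG at 24 h, and each exact permutation test gave p = 0.1 (adjusted p = 0.1), the smallest that 3 against 3 libraries allow. Conversions per labelled read were lower in 9 of 9, for example 1.12 ± 0.00142 against 1.3 ± 0.00377 at 6 h in the NSD1-dTAG line. As background, 0.457% to 1.00% of spike-in reads, which carry no 4sU, had a conversion. A single library's share had a 95% Wilson interval 0.0214 to 0.0314 points wide.

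**Figure D1:**
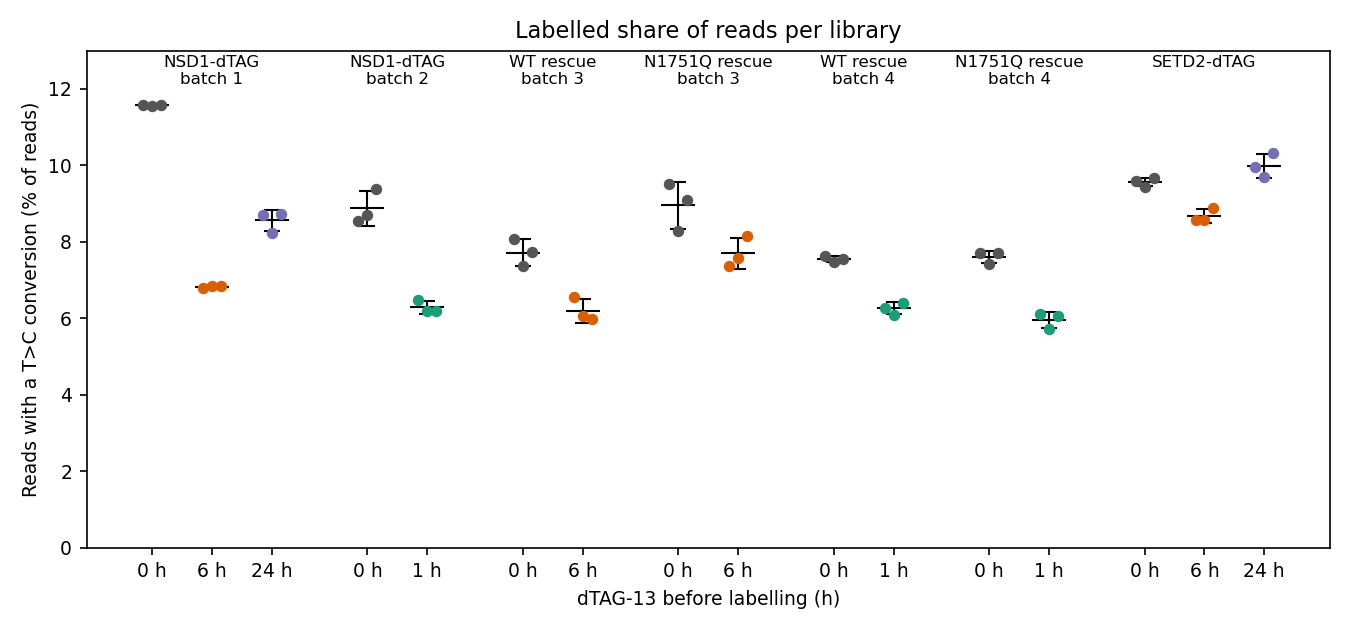
Reads with a T>C conversion, as percent of reads (y axis), in each of the 48 libraries (dots) by line, batch and hours of dTAG-13 (x axis), with horizontal bars for the mean and whiskers for the SD of 3 libraries. At 6 h in the NSD1-dTAG line the mean was 6.83% against 11.6% at 0 h, and SETD2-dTAG at 24 h, 9.99%, was the only treated group above its control.

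The genes of the degraded proteins were examined first. Nsd1 (chromosome 13, 55209782 to 55318325) had a log2 fold change in labelled reads of -0.19 at 1 h (edgeR adjusted p = 0.998), 0.25 at 6 h (adjusted p = 0.564) and -0.02 at 24 h (adjusted p = 0.992) in the NSD1-dTAG line. Setd2 (chromosome 9, 110532597 to 110618633) had 0.28 at 6 h (edgeR adjusted p = 0.451) and 0.08 at 24 h (adjusted p = 0.966) in the SETD2-dTAG line. Library sizes from all reads, which keep the weaker labelling, put Nsd1 at -0.51 at 6 h (edgeR adjusted p = 0.00440) and -0.44 at 24 h (adjusted p = 0.0339) in the NSD1-dTAG line, where the median gene had -0.76 and -0.42. Setd2 then had -0.79 at 6 h there (edgeR adjusted p = 1.47e-04). In the rescue lines the smallest edgeR adjusted p of either gene was 0.798, for Setd2 at 1 h with wild-type NSD1. The tag acts on protein, so these transcripts do not check whether degradation worked, and whether the counted 3' end is part of the NSD1 transgene was not given in the sources used here.

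The first question was which genes change transcription on acute loss of NSD1. After 6 h of dTAG-13 in the NSD1-dTAG line, new RNA of single pluripotency and signalling genes fell and that of the stress response list rose, relative to the bulk of genes. Of the 10 lists that passed with a preset correlation, 1, the stress response, held with an estimated correlation (limma camera adjusted p = 0.00426, against 0.115 for core pluripotency factors). Sox2, a core pluripotency factor (chromosome 3, 34650405 to 34652461), went from 2317 ± 141 to 1541 ± 153 labelled CPM, a log2 fold change of -0.59 (SE 0.09). Zfp42, also called Rex1 and a marker of naive pluripotency, fell by 0.58 on the log2 scale (SE 0.10) and Mycn, a proto-oncogene active in stem cells, by 0.77 (SE 0.14). Chac1, which degrades glutathione and is induced through ATF4 (chromosome 2, 119351229 to 119354381), rose from 13.7 ± 2.81 to 65.1 ± 5.93 CPM, a log2 fold change of 2.24 (SE 0.37). Slc3a2, the heavy chain of several amino acid transporters (chromosome 19, 8706882 to 8723369), rose from 580 to 1162 CPM. In all, 60 of 9694 genes passed edgeR, 28 higher and 32 lower.

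Among the genes called at 6 h, the largest increases after Chac1 were Ddit3, encoding the stress transcription factor CHOP, with a log2 fold change of 1.51 (SE 0.37, edgeR adjusted p = 0.0432), Hsd17b14, a hydroxysteroid dehydrogenase, with 1.19 (adjusted p = 0.000987), and Hsf2bp, a meiotic recombination factor, with 1.09 (adjusted p = 0.0379). Manf, a factor of the endoplasmic reticulum stress response (chromosome 9, 106838312 to 106891979), had 0.78 (edgeR adjusted p = 0.000987). The largest decreases were Bcdin3d, an RNA methyltransferase, with -1.65 (adjusted p = 0.0432), Trh, the thyrotropin-releasing hormone gene, with -1.12 (adjusted p = 0.0272), and Taf1d, a subunit of the RNA polymerase I initiation factor, with -1.11 (adjusted p = 0.00947). Camta1, Pnrc1 and Sp5, a Wnt target and transcription factor, had -0.93, -0.88 and -0.85. Both Polycomb genes called went apart: Epop, a protein bound to PRC2, had -0.77 (edgeR adjusted p = 0.00262) and Suz12, a core PRC2 subunit, 0.46 (adjusted p = 0.0174). Zic5 fell by 0.49, and Meis2, a homeodomain factor, by 0.71 on the log2 scale.

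Grouped by list, 22 of 24 measured stress response genes were above 0 at 6 h (median log2 fold change 0.46), and 4 were called, Chac1, Slc3a2, Ddit3 and Hsp90b1, a chaperone of the endoplasmic reticulum with 0.72 (edgeR adjusted p = 0.00328). Adjusted over the list alone, 13 rose and 1 fell. The list passed limma camera with an adjusted p of 1.27e-12, and with an adjusted p = 0.00426 with an estimated correlation. Core pluripotency factors had a median of -0.23 with 18 of 24 below 0. Sox2, Mycn, Id3 (-0.56) and Klf4 (-0.40) were called lower, and 10 were when adjusted over the list alone. Nanog had -0.38 (edgeR adjusted p = 0.0837) and Pou5f1, encoding OCT4, -0.18 (adjusted p = 0.621), and both were chosen after their values were seen. This list passed at adjusted p = 4.81e-05 in limma camera, but not with adjusted p = 0.115 with an estimated correlation. With each library's trend on the gene's 0 h labelled share removed, its median was -0.14 (camera adjusted p = 0.0253).

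Further lists passed lower at 6 h with the preset correlation. Naive pluripotency genes had a median of -0.09 (12 of 19 below 0, camera adjusted p = 0.0137, and adjusted p = 0.115 with an estimated correlation), with Zfp42, Klf4 and Nr0b1 called over all genes and 7 lower adjusted over the list alone. Wnt targets had -0.39 (12 of 14 below 0, adjusted p = 0.000559, and adjusted p = 0.0780 with an estimated correlation), with Sp5 and the growth factor gene Bmp4 (-0.48) called, and 1 higher and 5 lower adjusted over the list alone. BMP and TGF-beta/Nodal targets had -0.30 (11 of 14, camera adjusted p = 0.000432, and adjusted p = 0.115 with an estimated correlation). Smad7, an inhibitory SMAD with -0.78, and Id3, an inhibitor of bHLH factors, were called there, and 4 fell adjusted over the list alone. FGF/ERK targets had -0.08 (9 of 16, camera adjusted p = 0.0389, and adjusted p = 0.15 with an estimated correlation), with Dusp6, a phosphatase of ERK, called at -0.47 and 2 adjusted over the list alone. Immediate early genes had -0.29 (14 of 18, adjusted p = 0.00247, and adjusted p = 0.115 with an estimated correlation) with 1 adjusted over the list alone, and p53 targets -0.23 (15 of 23, adjusted p = 0.0171, and adjusted p = 0.115 with an estimated correlation) with 3. Ribosomal protein genes had -0.14 (40 of 53, adjusted p = 0.00301, and adjusted p = 0.544 with an estimated correlation), with Rpl4 called at -0.46 and 3 higher and 9 lower adjusted over the list alone. Germline genes under DNA methylation were higher, with 0.42 (9 of 10 above 0, adjusted p = 0.01, and adjusted p = 0.151 with an estimated correlation), none called over all genes and 1 adjusted over the list alone. With the labelling trend removed, the calls of naive genes (adjusted p = 0.212), FGF/ERK targets (0.578), immediate early genes (0.167) and p53 targets (0.29) ended. Sgk1, a kinase on the LIF/STAT3 list, fell by 0.54 on the log2 scale (edgeR adjusted p = 0.000912).

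In all reads, which include the labelled ones, all 60 genes changed in the same direction and 21 of them also passed, 5 higher and 16 lower. Chac1, Sox2 and Zfp42 were called on labelled reads in all of their alternative settings. The number called was 25, 15 and 13 without 0 h replicates 1, 2 and 3, and 21 and 16 without 6 h replicates 1 and 2, and 22 in a joint fit of all libraries, but 139 by DESeq2 and 133 in a fit of only both groups. Library sizes from all reads, which keep the weaker labelling, moved the median gene to -0.76 and the calls to 4 higher and 5188 lower, ERCC reads gave 6 and 3411, and removal of the trend on labelled share gave 27 and 19, so every change here is relative to the bulk of genes. In the other 8 comparisons that median ran from -0.51 to 0.08. The stress response list then had -0.30, still above the bulk (camera adjusted p = 0.00831). Under all-read scaling Hsp90b1 (-0.03) and Suz12 (-0.29) took the opposite sign, as did Suz12 (-0.09) under ERCC scaling, but both lay above the bulk.

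At 24 h in the NSD1-dTAG line few single genes differed from 0 h, and developmental regulators were lower as a group. Meis2 fell by 0.84 on the log2 scale (SE 0.17, edgeR adjusted p = 0.0328), from 225 ± 35.8 to 126 ± 26.2 labelled CPM. Nr0b1, encoding the nuclear receptor DAX1 of the naive state, rose by 0.50 (SE 0.10, edgeR adjusted p = 0.0328), and the ribosomal protein genes Rpl14 by 0.62 and Rpl8 by 0.47. Of 9694 genes 7 passed, 6 higher and 1 lower. The other calls were mt-Tm, a mitochondrial tRNA gene, and the ribosomal gene copies Rpl10-ps3 and Rps27rt, with 0.87, 0.77 and 0.70, which share sequence with other loci and are uncertain.

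All 11 measured bivalent developmental regulators lay below 0 at 24 h, with a median of -0.84 (limma camera adjusted p = 7.14e-07, and adjusted p = 0.0337 with an estimated correlation). Meis2 was called, and 2 adjusted over the list alone. Hoxa3 (-1.86), Hoxa5 (-1.78), Evx1 (-1.39) and Msx2 (-1.36) did not pass singly and were chosen after their values were seen. Stress response genes stayed higher, with a median of 0.21 and 21 of 24 above 0 (camera adjusted p = 0.00142, and adjusted p = 0.0775 with an estimated correlation), none called over all genes. Ribosomal protein genes were higher, 0.20 with 49 of 53 above 0 (adjusted p = 1.31e-11, and adjusted p = 0.328 with an estimated correlation), and adjusted over the list alone 12 rose and 1 fell. Under all-read scaling the stress list had -0.20 (adjusted p = 0.189) and ribosomal protein genes -0.23 (adjusted p = 0.858), and with the labelling trend removed ribosomal protein genes had 0.03 (adjusted p = 0.147). In the direct test of 24 h against 6 h, 134 genes differed, 84 higher and 50 lower. Sox2 was 0.62 higher (edgeR adjusted p = 1.34e-04), Nr0b1 0.93 (adjusted p = 6.50e-07), and Mycn, Zfp42, Id3, Smad7 and Foxd3 0.99, 0.61, 0.67, 0.82 and 0.79 on the log2 scale. All these genes were called lower from the same 6 h libraries, so selection may explain part of the rise, and the labelling trend was kept. Nr6a1 was lower, with -1.15 (edgeR adjusted p = 2.87e-05), as were Top1 (-0.90), Prc1, a cytokinesis factor (-0.74), and Txnip (-0.62). Genes of this test are those with the smallest adjusted p and some called at 6 h, chosen after their values were seen.

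Without single libraries the 24 h count was 0, 2 and 0 for 0 h replicates 1, 2 and 3, and 11 and 1 for 24 h replicates 1 and 3. A joint fit of all libraries called 0, but DESeq2 called 34. All-read scaling gave 4 higher and 1774 lower, ERCC scaling 4 and 1891, removal of the labelling trend 2 and 0, and removal of the T content trend 6 and 3. For 24 h against 6 h the count was 36 and 77 without 6 h replicates 1 and 2 and 36 without 24 h replicate 2, and all-read scaling gave 1464 higher and 27 lower.

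At 1 h no single gene passed in the NSD1-dTAG line, while cholesterol and stress response genes were higher as groups with the preset correlation only. Of the cholesterol biosynthesis genes 21 of 24 lay above 0, with a median log2 fold change of 0.30 (limma camera adjusted p = 2.17e-05, and adjusted p = 0.0864 with an estimated correlation). Stress response genes had 0.31 with 20 of 23 above 0 (camera adjusted p = 5.71e-05, and adjusted p = 0.0864 with an estimated correlation), and no member of either list was called. Among 8719 genes edgeR called 0, with 336 at an unadjusted p under 0.05, and DESeq2 also called 0. All-read scaling called 222, all lower, and put the cholesterol list at -0.19 (camera adjusted p = 0.0577), and the joint fit of all libraries 11.

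The rescue lines ask whether a response depends on NSD1 and on its catalytic activity. With wild-type NSD1 present, the stress response list was also higher at 6 h of dTAG-13. Of 7 lists that passed with a preset correlation it was the 1 that held with an estimated correlation. Stress response genes had a median of 0.26, with 23 of 25 above 0 (limma camera adjusted p = 3.59e-07, and adjusted p = 0.00590 with an estimated correlation), 0 called over all genes and 5 adjusted over the list alone. Its member Psat1, of serine synthesis, had 0.63 (edgeR adjusted p = 0.0872) and was chosen after its values were seen. Single genes called were 9 of 9212, 3 higher and 6 lower. Sgk1 fell by 0.47 on the log2 scale (SE 0.09, edgeR adjusted p = 0.0263), from 3021 ± 49.3 to 2179 ± 190 labelled CPM, Cdkn1a, encoding the cell cycle inhibitor p21, by 0.74 (SE 0.14, adjusted p = 0.0263), and Actb, encoding beta-actin, by 0.52. Higher were Mrpl48, a mitochondrial ribosome gene, with 1.98, Pmpca, a mitochondrial protease gene, with 0.89, and Zfp518a with 0.72. Hist1h2ae (-1.63) and Olfr1388 (-0.52) belong to large gene families and are uncertain.

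Core pluripotency factors were lower with wild-type NSD1, with a median of -0.15 and 21 of 25 below 0 (limma camera adjusted p = 0.00652, and adjusted p = 0.252 with an estimated correlation). Formative and primed genes had -0.38 and BMP and TGF-beta/Nodal targets -0.22 (camera adjusted p = 0.00652 each, and adjusted p = 0.0890 each with an estimated correlation). Immediate early genes had -0.29 (adjusted p = 0.00733), LIF/STAT3 targets -0.13 (adjusted p = 0.00867) and FGF/ERK targets -0.17 (adjusted p = 0.0113), each lost at adjusted p = 0.373 with an estimated correlation. Removal of the labelling trend ended the calls of core factors and immediate early genes (adjusted p = 0.0919 each), FGF/ERK targets (0.122) and LIF/STAT3 targets (0.164). Without 0 h replicates 1, 2 and 3 of this line the count of called genes was 0, 1 and 4, and without 6 h replicate 1 it was 14. ERCC scaling and a fit of only both groups called 0 each, the joint fit 1, all-read scaling 3 higher and 587 lower, DESeq2 10 and 11, and removal of the labelling trend 4 and 4.

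With the N1751Q form no single gene passed at 6 h, and the stress response list was again higher, with a median of 0.21 and 21 of 25 above 0 (limma camera adjusted p = 5.21e-08, and adjusted p = 0.00461 with an estimated correlation, 8 adjusted over the list alone). Core pluripotency factors had -0.11 with 17 of 25 below 0 (camera adjusted p = 0.0150, and adjusted p = 0.473 with an estimated correlation), BMP and TGF-beta/Nodal targets -0.24 (adjusted p = 0.0144), and ribosomal protein genes -0.19 with 51 of 54 below 0 (1.77e-09), both lost at adjusted p = 0.165 and 0.473 with an estimated correlation. Removal of the labelling trend ended the calls of core factors (adjusted p = 0.418) and BMP and TGF-beta/Nodal targets (0.149). EdgeR called 0 of 9212 genes, with 526 at an unadjusted p under 0.05, DESeq2 called 0, and 1 was called without 6 h replicate 1. A fit of only both groups called 8 higher and 14 lower, and all-read scaling 42, all lower.

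Differences between the rescue lines' responses were tested directly. N1751Q minus wild-type gave 0 genes in edgeR at 6 h (527 at an unadjusted p under 0.05, 0 by DESeq2) and 0 at 1 h (448 and 0). No transgene minus wild-type gave 12 genes at 6 h, 5 higher and 7 lower. Chac1 rose more without transgene, by 1.83 on the log2 scale (SE 0.35, edgeR adjusted p = 0.00926). Its 0 h labelled reads per library were 24 to 38 there and 78 to 109 in the rescue. Troap (1.41), Mfsd10 (1.31) and Suz12 (0.71) were relatively higher, and Bcdin3d (-2.52), Slc39a11 (-1.77), Dstn (-1.03) and Dact2 (-0.79) lower. Against N1751Q 2 differed, Depdc1b (-3.54, adjusted p = 0.0234) and Slc39a11 (-1.65, adjusted p = 0.0296). At 1 h, the line without transgene differed in 0 genes from wild-type (663 at an unadjusted p under 0.05, 1 by DESeq2) and in 0 from N1751Q (321 and 0). The stress response list did not differ between the line without transgene and wild-type at 6 h (camera adjusted p = 0.358), which does not show that they responded alike. The 6 h count against wild-type was 7, 6 and 30 without NSD1-dTAG 0 h replicate 3 and 6 h replicates 1 and 3, 4 and 2 without rescue 0 h replicates 1 and 2, and 28 and 7 without rescue 6 h replicates 1 and 3, and all-read scaling gave 9 higher and 1013 lower. Against N1751Q at 6 h no gene was called by edgeR without NSD1-dTAG 0 h replicate 1 or 3 or 6 h replicate 3, any N1751Q 0 h replicate or N1751Q 6 h replicate 1, and 1 was without NSD1-dTAG 0 h replicate 2 or 6 h replicate 1. At 1 h against wild-type 3 were called without NSD1-dTAG 1 h replicate 1 and 1 without wild-type 0 h replicate 1, and N1751Q minus wild-type at 6 h had 1 without N1751Q 6 h replicate 1.

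After 1 h, rescue lines showed list changes without single genes past the threshold. With wild-type NSD1 the stress response list had a median of 0.32, with 20 of 24 above 0 (limma camera adjusted p = 3.98e-06, and adjusted p = 0.0124 with an estimated correlation, 7 adjusted over the list alone). P53 targets had -0.35 (16 of 23 below 0, adjusted p = 0.00366, and adjusted p = 0.0609 with an estimated correlation) and ribosomal protein genes -0.23 (45 of 54, adjusted p = 4.13e-08, and adjusted p = 0.275 with an estimated correlation). In the N1751Q line cholesterol biosynthesis genes had 0.30 with 21 of 24 above 0 (camera adjusted p = 1.41e-09, and adjusted p = 0.00229 with an estimated correlation), 2 of them past the threshold adjusted over the list alone. Insig1, a sterol sensor regulator (0.68), Cyp51 (0.61) and Lss (0.60), enzymes of the pathway, were chosen after their values were seen. Stress response genes had 0.32 with 19 of 24 above 0 (camera adjusted p = 2.41e-06, and adjusted p = 0.00551 with an estimated correlation, 3 adjusted over the list alone), BMP and TGF-beta/Nodal targets -0.20 (adjusted p = 0.0328) and ribosomal protein genes -0.13 (0.00962), both lost at adjusted p = 0.267 and 0.523 with an estimated correlation. Removal of the labelling trend ended the calls of p53 targets with wild-type NSD1 (adjusted p = 0.091) and BMP and TGF-beta/Nodal targets with N1751Q (0.181). Among 9369 genes edgeR called 0 with wild-type NSD1 (727 at an unadjusted p under 0.05, 12 by DESeq2, 8 higher and 4 lower) and 0 with N1751Q (214 and 1). With wild-type NSD1, 3 were called without 0 h replicate 1, 4 without 1 h replicate 3, 53 in the joint fit and 131 with all-read scaling, and with N1751Q ERCC scaling called 231, all lower.

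**Figure D2:**
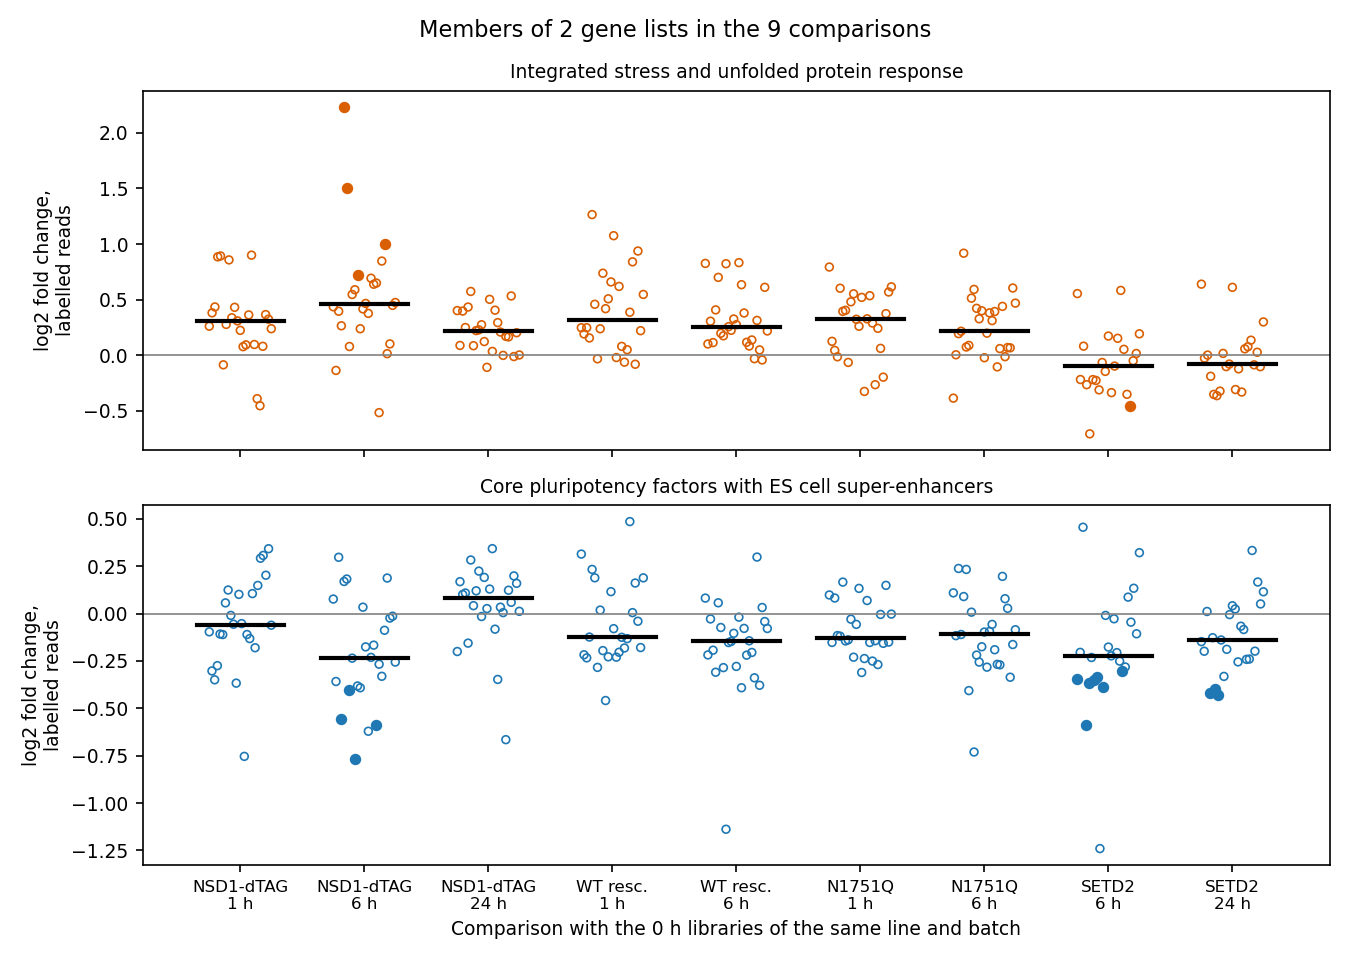
Log2 fold change in labelled reads (y axis) of each measured member of the stress response list (top) and the core pluripotency list (bottom) in the 9 comparisons with 0 h (x axis), with filled dots for members called by edgeR, open dots for the others and black bars for the median. At 6 h in the NSD1-dTAG line the medians were 0.46 and -0.23, relative to the bulk of genes.

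Before any dTAG-13, the N1751Q and wild-type rescue lines differed in each batch, and few genes were called in both batches. Since the tags of the lines differ between these batches, batch and clone cannot be separated here. In batch 3, 186 of 9212 genes differed in labelled reads, 107 higher and 79 lower with N1751Q. Tbx18, a T-box factor (4.81), Rgma, a guidance molecule (3.66), Crip1 (3.06), Tns1 (2.96), Ube2l6 (2.74) and Tex13b (2.70) were the highest, and Pik3cd, a PI3-kinase subunit (-2.85), Pea15a (-2.80), Depdc1b (-2.35), Stard8 (-2.30), Bag2 (-2.30) and Pla2g1b (-2.24) the lowest in log2 fold change. In batch 4, 21 of 9369 differed, 10 higher and 11 lower. Capn1, a calpain protease (4.26), Nrros (3.81), Zfp229 (2.41), Gpt2 (1.86), Cmklr1 (1.47) and the pseudogene Rpl10-ps3 (1.53, uncertain) were higher, and Ube2l6 (-3.42), Tpbg (-2.11), Ccn2 (-1.31), Pttg1 (-1.21) and Phb2 (-1.20) lower. Zfp229 was the 1 gene higher in both batches (1.39 in batch 3, edgeR adjusted p = 3.52e-06 and 9.29e-06), and none was lower in both. Equal chances per gene would give 0.112 higher. Ube2l6 and Tpbg (1.95 in batch 3) were among 3 higher in batch 3 and lower in batch 4, and Mthfd2, chosen after its values were seen, was -0.55 in batch 3 and 0.75 in batch 4. Of 177 genes called in batch 3 and tested in both, 66 had the same sign. The batch 3 count was 91 and 107 without wild-type replicates 1 and 2 and 102, 111 and 98 without N1751Q replicates 1, 2 and 3, and all-read scaling gave 630 higher and 41 lower. In batch 4 it was 11 without wild-type replicate 2 and 12 and 8 without N1751Q replicates 2 and 3.

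After 6 h of dTAG-13 in the SETD2-dTAG line core, naive and formative pluripotency genes and LIF/STAT3 targets were lower, relative to the bulk of genes (limma camera adjusted p of 0.0381 to 0.0494 with an estimated correlation). The calls of naive genes and LIF/STAT3 targets ended with the labelling trend removed (adjusted p = 0.0518 and 0.147). BMP and TGF-beta/Nodal, FGF/ERK and Wnt targets passed with the preset correlation only. The stress response list did not pass (median -0.10, camera adjusted p = 0.0549). Id3 (chromosome 4, 136143497 to 136145755) fell from 815 ± 70.1 to 542 ± 27.7 labelled CPM, a log2 fold change of -0.59 (SE 0.09, edgeR adjusted p = 8.40e-05). Sox2 fell by 0.30 (SE 0.06), Jarid2, a PRC2 cofactor, by 0.37 (SE 0.07), Klf4 by 0.35 (SE 0.08), Esrrb, a nuclear receptor of naive pluripotency, by 0.35 and Spry4, a feedback inhibitor of ERK signalling, by 0.60 (SE 0.12). The largest decreases were Gprc5b (-2.15), Zic2, a transcription factor of the formative state (-1.31), Frmd4b (-1.06), Ccnjl (-1.0), Slc29a2, a nucleoside transporter gene (-0.98), and Sox21 (-0.95). Highest were Tbck (2.21), Tbccd1 (1.70), Mapk4 (1.22), Virma, a subunit of the RNA m6A methyltransferase (1.08), Brca2, of homologous recombination (0.87), and Tnks, a poly-ADP-ribose polymerase (0.80). In all, 81 of 9015 genes passed edgeR, 19 higher and 62 lower.

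Core pluripotency factors had a median of -0.22 at 6 h in the SETD2-dTAG line, with 19 of 23 below 0 (limma camera adjusted p = 2.80e-07, and adjusted p = 0.0381 with an estimated correlation). Of these 7 were called over all genes, among them Klf9 (-0.33), and adjusted over the list alone 10 fell and 1 rose. Nanog had -0.01 (edgeR adjusted p = 0.983), chosen after its value was seen. LIF/STAT3 targets had -0.22 with 10 of 12 below 0 (camera adjusted p = 1.17e-04), with the kinases Pim1 (-0.38) and Sgk1 (-0.29), Klf4 and Socs3 (-0.27), a feedback inhibitor of STAT3, among 5 called, and adjusted over the list alone 7 fell and 1 rose. Naive pluripotency genes had -0.17 (15 of 18, adjusted p = 8.70e-04, 6 adjusted over the list alone), formative and primed genes -0.42 (12 of 15, adjusted p = 0.00245, 3 adjusted over the list alone), cholesterol biosynthesis genes -0.25 (16 of 21, adjusted p = 0.00127, 2 adjusted over the list alone), and nucleolar and ribosome biogenesis factors -0.21 (18 of 21, adjusted p = 7.87e-04, 4 adjusted over the list alone). Of these, formative genes held at adjusted p = 0.0494 with an estimated correlation and the other 4 at adjusted p = 0.0473. Hmgcs1, an enzyme of cholesterol synthesis, was called lower (-0.44).

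Some lists passed at 6 h in the SETD2-dTAG line only with the preset correlation. BMP and TGF-beta/Nodal targets had -0.39 (12 of 14 below 0, limma camera adjusted p = 1.10e-04, and adjusted p = 0.0700 with an estimated correlation), with 5 lower and 1 higher adjusted over the list alone. FGF/ERK targets had -0.28 (10 of 15, camera adjusted p = 0.00558, and adjusted p = 0.111 with an estimated correlation), with Spry4 and Ccnd1, encoding cyclin D1 (-0.47), called and 3 adjusted over the list alone. Wnt targets had -0.22 (8 of 12, adjusted p = 0.0252, and adjusted p = 0.25 with an estimated correlation), with 4 lower and 1 higher adjusted over the list alone. Immediate early genes had -0.18 (16 of 19) and ribosomal protein genes were higher, 0.08 with 34 of 47 above 0 (adjusted p = 0.00762 each, and adjusted p = 0.111 and 0.605 with an estimated correlation). From other lists, Ldha, lactate dehydrogenase (-0.65), Slc3a2 (-0.46), Cdkn1a (-0.44) and the replication gene Mcm5 (-0.44) were called lower. Removal of the labelling trend also ended the calls of Wnt (adjusted p = 0.107), FGF/ERK (0.452), immediate early (0.946) and ribosomal protein genes (0.582). In all reads 80 of the 81 genes had the same sign and 23 also passed. The count was 26, 17 and 47 without 0 h replicates 1, 2 and 3 and 38, 22 and 174 without 6 h replicates 1, 2 and 3. The joint fit called 5, ERCC scaling 0, a fit of only both groups 31, DESeq2 80 higher and 121 lower and all-read scaling 7 and 175.

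At 24 h in the SETD2-dTAG line 12 genes differed from 0 h, 4 higher and 8 lower. Cited2, a CBP/p300-binding coactivator (chromosome 10, 17723218 to 17725674), fell from 319 ± 28.8 to 163 ± 24.8 labelled CPM, a log2 fold change of -0.97 (SE 0.13, edgeR adjusted p = 7.24e-06). Klf4 (-0.43) and Klf2 (-0.40), factors of naive pluripotency, Id3 (-0.42) and Gnl3, encoding nucleostemin (-0.32), were lower, and the mitochondrial tRNA gene mt-Tg (-0.54) is uncertain. Hunk, a kinase (0.66), Msc, a bHLH factor (0.62), Ahdc1 (0.53) and Lmnb1, encoding lamin B1 (0.35), were higher. Core pluripotency factors had a median of -0.14 (16 of 23 below 0, limma camera adjusted p = 2.88e-04, and adjusted p = 0.108 with an estimated correlation, 5 adjusted over the list alone), LIF/STAT3 targets -0.22 (11 of 12, adjusted p = 1.98e-04, and adjusted p = 0.108 with an estimated correlation, 4 adjusted over the list alone), and BMP and TGF-beta/Nodal targets -0.37 (10 of 14, adjusted p = 0.00102, and adjusted p = 0.214 with an estimated correlation, 3 adjusted over the list alone). Nucleolar factors had -0.09 (16 of 21, adjusted p = 0.00988) and trophoblast genes 0.36 with 7 of 7 above 0 (0.0279, 0 called), both lost at adjusted p = 0.120 and 0.452 with an estimated correlation. Removal of the labelling trend ended the calls of core factors (adjusted p = 0.451) and of LIF/STAT3 and BMP and TGF-beta/Nodal targets (0.44 each), and all-read scaling those of trophoblast genes (0.0584) and nucleolar factors (0.126). Against 6 h, 10 genes differed, 9 higher and 1 lower: Msc (0.94), Ak4 (0.66), Hmces (0.56), Ppp1r10 (0.55), Slc30a1 (0.54), Etv5 (0.45), Nr0b1 (0.44), Bmp4 (0.43) and Mif (0.41) were higher, and the lower gene has no given name; these were chosen after their values were seen. The 24 h count was 4 without 0 h replicate 2 and 6 without 24 h replicate 1. The joint fit called 7, DESeq2 30 higher and 39 lower, ERCC scaling 0 and 1, all-read scaling 5 and 4 and removal of the labelling trend 9 and 6. Against 6 h the count was 3, 5 and 83 without 6 h replicates 1, 2 and 3, 3, 5 and 4 without 24 h replicates 1, 2 and 3, and 25 higher and 25 lower by DESeq2.

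**Figure D3:**
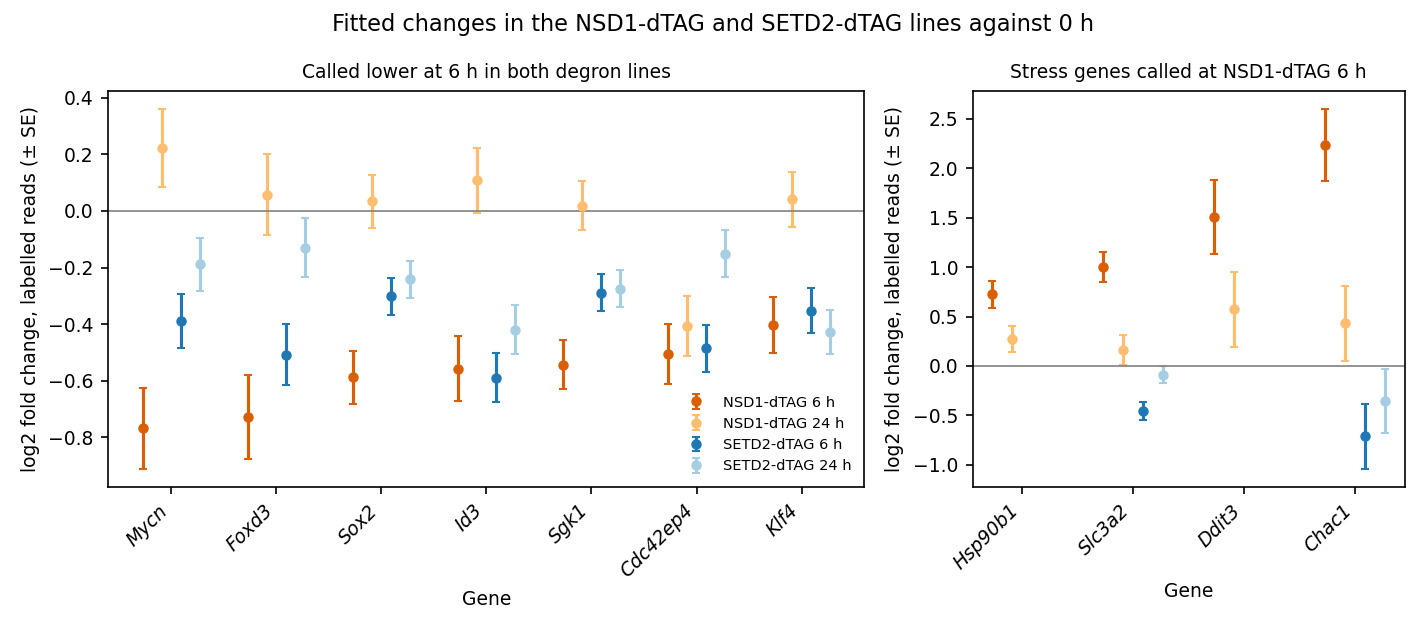
Fitted log2 fold change against 0 h with its SE (y axis) in both degron lines at 6 and 24 h (colours), for the 7 genes called lower at 6 h in both lines (left) and the 4 stress response genes called at 6 h in the NSD1-dTAG line (right). At 6 h Chac1 had 2.24 in the NSD1-dTAG line, and Hsp90b1 and Ddit3 were tested only there.

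Genes called at 6 h in the NSD1-dTAG line were then followed in the other comparisons, which use other 0 h libraries. The 32 genes called lower at 6 h had a median of -0.22 at 6 h in the SETD2-dTAG line, 24 of 29 below 0 (limma camera adjusted p = 7.70e-10, and adjusted p = 0.00707 with an estimated correlation). Removal of the labelling trend put them at -0.09 there (19 of 29 below 0, adjusted p = 0.00748, and adjusted p = 0.0490 with an estimated correlation), and all reads at -0.05 (18 of 29, adjusted p = 0.00406, and adjusted p = 0.166 with an estimated correlation). They had a median of -0.22 at 6 h with N1751Q, 28 of 32 below 0 (adjusted p = 4.66e-13, and adjusted p = 0.00797 with an estimated correlation). With wild-type NSD1 at 6 h they had -0.14 (24 of 32, adjusted p = 0.00141, and adjusted p = 0.165 with an estimated correlation). In both degron lines 0 genes were called higher at 6 h and 7 lower: Klf4, Id3, Sgk1, Mycn, Sox2, Cdc42ep4 and Foxd3. The last 2 were chosen after their values were seen. Equal chances for all genes, a poor guide as depth and labelling differ, would give 0.0437 and 0.218. The 28 genes called higher had a median of 0.16 at 6 h with N1751Q (25 of 28 above 0, camera adjusted p = 1.40e-09, and adjusted p = 0.0110 with an estimated correlation), 0.37 at 1 h with wild-type NSD1 (27 of 28, adjusted p = 1.89e-09, and adjusted p = 0.0605 with an estimated correlation) and 0.08 at 6 h with wild-type NSD1 (20 of 28, adjusted p = 0.00505, and adjusted p = 0.165 with an estimated correlation). All-read scaling put them at -0.07 at 6 h with N1751Q (12 of 28 above 0, adjusted p = 2.77e-04, and adjusted p = 0.169 with an estimated correlation). In all reads the higher genes had -0.06 at 6 h with wild-type NSD1 (20 of 28 below 0, adjusted p = 0.162) and 0.03 with N1751Q (17 of 28 above 0, adjusted p = 0.00996, and adjusted p = 0.311 with an estimated correlation). In the SETD2-dTAG line the higher genes had -0.04 at 6 h (adjusted p = 0.18). At 1 h with wild-type NSD1 and with N1751Q the lower genes had -0.16 (adjusted p = 4.49e-04) and -0.12 (0.00681), and the higher genes 0.09 with N1751Q (6.37e-04). These calls were lost at adjusted p = 0.0777, 0.156 and 0.156 with an estimated correlation. At 24 h in the SETD2-dTAG line the medians were -0.13 for lower genes (adjusted p = 0.00640) and -0.01 for higher genes, whose camera direction was the reverse (0.00819), with adjusted p = 0.143 and 0.164 with an estimated correlation. With the labelling trend removed, the calls of lower genes ended at 6 h and 1 h with wild-type NSD1 (adjusted p = 0.0555 and 0.0843), at 1 h with N1751Q (0.110) and at 24 h in the SETD2-dTAG line, where the direction turned (0.278). All-read scaling ended those of higher genes at 6 h with wild-type NSD1 (0.783) and 1 h with N1751Q (0.561) and of both sets at 24 h in the SETD2-dTAG line (0.0948 each). At 1 h without transgene neither set passed (-0.02, adjusted p = 0.135, and 0.01, adjusted p = 0.0953). Across genes, which are not independent replicates, the Spearman correlation of 6 h changes between the degron lines was 0.0252.

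Responses to dTAG-13 in the NSD1-dTAG and SETD2-dTAG lines were compared by interaction tests. At 6 h 26 of 9925 genes differed, 19 higher and 7 lower in NSD1 minus SETD2. Chac1 had 2.93 on the log2 scale (SE 0.50, edgeR adjusted p = 0.00163), Manf 0.81 (adjusted p = 0.0150), Txnip 0.81 and Gtpbp1 1.61 (adjusted p = 0.0498). Lower were Smim15 (-0.98), M6pr, a lysosomal enzyme receptor gene (-0.97), and Dclk3 (-4.25), whose labelled reads were 1, 0 and 3 at 6 h and 22, 29 and 34 at 0 h in the NSD1-dTAG line. At 24 h 18 genes differed, 12 higher and 6 lower: Cited2 (1.00, adjusted p = 0.00444) and Klf2 (0.67) were higher, with the uncertain mt-Tm (1.47) and Rps27rt (0.97), and Msc (-1.23, adjusted p = 1.05e-04), Rbm47 (-1.56) and Top1 (-1.03) lower. Manf, Txnip, Klf2 and Top1 were chosen here after their values were seen. Lists differed too, first the stress response at 6 h with a median difference of 0.39, 19 of 22 above 0 (limma camera adjusted p = 3.23e-07, and adjusted p = 0.00114 with an estimated correlation), and bivalent regulators at 24 h with -1.06, 13 of 14 below 0 (adjusted p = 0.00593, and adjusted p = 0.0482 with an estimated correlation). The 6 h count was 48, 8, 12 and 66 without NSD1-dTAG 0 h replicates 1 and 3 and 6 h replicates 1 and 3, and 17, 15, 14 and 95 without SETD2-dTAG 0 h replicates 1 and 2 and 6 h replicates 1 and 3. The 24 h count was 10 without SETD2-dTAG 0 h replicate 3. All-read scaling gave 9 higher and 2265 lower at 6 h and 5 and 887 at 24 h, and DESeq2 95 and 65 at 6 h.

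In all reads, which add older RNA, glycolysis genes fell at 6 h in both degron lines. In the NSD1-dTAG line the hypoxia and glycolysis list had a median of -0.24 with 22 of 25 below 0 (limma camera adjusted p = 1.13e-14, and adjusted p = 0.00207 with an estimated correlation), 7 called and 9 adjusted over the list alone. Slc16a3, a lactate exporter, had -2.25 (edgeR adjusted p = 4.46e-11), Bnip3, of mitophagy, -1.20, Ldha -0.61, the glucose transporter gene Slc2a1 -0.45 and the glycolytic enzyme gene Pgk1 -0.41. In the SETD2-dTAG line the list had -0.18 with 16 of 20 below 0 (camera adjusted p = 3.00e-09, and adjusted p = 0.0125 with an estimated correlation), and Slc16a3 had -2.03 (edgeR adjusted p = 1.48e-08). Germline genes under DNA methylation rose at 6 h in the NSD1-dTAG line, 0.48 with 16 of 16 above 0 (adjusted p = 5.42e-07, and adjusted p = 0.0109 with an estimated correlation), with Fkbp6 (0.82) and Dazl (0.73) called and 7 adjusted over the list alone. The naming rule covers labelled reads, so the genes of this paragraph were chosen after their values were seen.

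Stress response genes had 0.38 in all reads at 6 h in the NSD1-dTAG line (23 of 26 above 0, limma camera adjusted p = 3.03e-16, and adjusted p = 0.00207 with an estimated correlation), with 10 called and 14 adjusted over the list alone. Formative and primed genes had -0.31 (adjusted p = 4.62e-04, and adjusted p = 0.0316 with an estimated correlation), with Lef1, a Wnt effector (-1.07), Sox4 (-0.61), Igfbp2 (-0.59) and Ncam1 (-0.46) called. Wnt targets had a median of -0.27 but a mean of 0.07 (13 of 17 below 0, adjusted p = 8.97e-05, and adjusted p = 0.0273 with an estimated correlation). Core pluripotency factors had -0.12 with 18 of 25 below 0 (adjusted p = 7.43e-04, and adjusted p = 0.0812 with an estimated correlation), 5 called lower and Jarid2 higher. At 24 h all 8 genes of the 2-cell-like state lay below 0, with a median of -1.61 (camera adjusted p = 1.48e-05, and adjusted p = 0.0552 with an estimated correlation), none called over all genes. This list had too few members with labelled reads to be tested there. The all-read genes named here were again chosen after their values were seen.

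All-read calls were 153 of 13106 genes at 6 h in the NSD1-dTAG line (84 higher, 69 lower) and 62 at 24 h (26 and 36), and 278 of 11990 at 6 h (126 and 152) and 75 at 24 h (41 and 34) in the SETD2-dTAG line, all by edgeR. With wild-type NSD1 at 6 h 2 of 13598 were called, Sgk1 and Cacna1a, both lower and chosen after their values were seen. EdgeR called 0 at 1 h without transgene (380 at an unadjusted p under 0.05, 1 by DESeq2), 0 at 6 h with N1751Q (555 and 0), 0 at 1 h with wild-type NSD1 (895 and 2) and 0 at 1 h with N1751Q (264 and 0). Counts without single libraries were 32, 32, 38 and 43 for 0 h replicates 2 and 3 and 6 h replicates 1 and 2 of the NSD1-dTAG 6 h comparison, 16, 14 and 16 for the 0 h and 123, 112 and 17 for the 24 h libraries of the 24 h comparison, 15 and 35 for SETD2-dTAG 0 h replicates 1 and 2, 77, 11 and 1258 for its 6 h replicates 1, 2 and 3, and 22, 31 and 49 for the 0 h and 26, 24 and 23 for the 24 h libraries of its 24 h comparison. With wild-type NSD1 at 6 h they were 0, 1 and 12 for the 0 h and 8, 1 and 11 for the 6 h libraries.

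Several lists passed in none of the 9 comparisons on labelled reads. Their smallest adjusted p in limma camera was 0.0549 for primitive streak and mesoderm, 0.0781 for heat shock, 0.143 for hypoxia and glycolysis, 0.169 for cell cycle and replication, 0.263 for H3K36 methyltransferases, demethylases and readers, 0.295 for pause release and elongation, 0.352 for primitive endoderm, 0.357 for both the interferon response and fibroblast and extracellular matrix genes, 0.367 for PRC1 and PRC2 subunits, and 0.392 for both neural and imprinted genes. In all reads at 6 h in the NSD1-dTAG line the H3K36 list had a median of 0.15 with 19 of 21 above 0 (adjusted p = 0.0376, and adjusted p = 0.132 with an estimated correlation).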

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

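Tests of the stress and core pluripotency lists against loss of NSD1, of the stress list against dTAG-13 in any line, hidden or not, of core factors in all reads and of background beyond 6 h of the NSD1-dTAG line, in genes and in spike-ins, and all counts over other splits of the libraries, were chosen only after the results were seen.

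The labelled read share was lower under dTAG-13 in 8 of 9 comparisons, conversions per labelled read in 9 of 9. Fewer new reads at an unchanged conversion rate would leave the share of short-lived genes, whose reads are mostly new, nearly as it was, but in the 100 genes with the highest share in 0 h libraries of the SETD2-dTAG line it was 28.1% ± 0.45 against 49.7% ± 0.633 at 6 h in the NSD1-dTAG line, a ratio of 0.566 against 0.590 over all genes, as a lower conversion rate per new read would give. Background conversions weighing more would need 4.27% of reads there, above the 2.52% that the 5th percentile of 6469 well-covered genes showed. At 6 h in the SETD2-dTAG line 2.82% would be needed against 3.12% in genes and 0.681% ± 0.0763 in spike-ins, so there and at 24 h in both lines background of the kind spike-ins carry was too small, and background that spike-ins lack, such as sequence variants, stays open. A candidate explanation is a lower conversion rate per new T in treated cells, and no value here separates 4sU uptake from the iodoacetamide reaction.

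Core pluripotency factors were lower at 6 h in the NSD1-dTAG line, median -0.23 (limma camera adjusted p = 4.81e-05, and adjusted p = 0.115 with an estimated correlation). All reads argue against a change of labelling without a change of RNA level: 5 members were called lower, with Jarid2 higher, and the list's median was -0.12, a call lost at adjusted p = 0.0812 with an estimated correlation. A labelling trend across genes may account for part: with the trend removed the list kept an adjusted p of 0.0253 in limma camera, but its median went to -0.14. Loss of NSD1 alone and an effect of dTAG-13 on labelling or cells cannot be told apart for this list, since it was also lower with wild-type NSD1 (adjusted p = 0.00652, but 0.252 with an estimated correlation and 0.0919 with the trend removed) and at 6 h in the SETD2-dTAG line, whose NSD1 is untagged but where loss of SETD2 may act (median -0.22, 19 of 23 below 0, adjusted p = 2.80e-07, and 0.0381 with an estimated correlation). A response to loss of NSD1 stays open as a hypothesis.

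Stress response genes were higher, relative to the bulk of genes, under dTAG-13 in the NSD1-dTAG line and both its rescue lines. The labelling trend was excluded as the whole cause, since the list kept an adjusted p of 6.17e-14 in limma camera without it at 6 h in the NSD1-dTAG line. Loss of NSD1 alone was excluded too, since the list was higher with wild-type NSD1 at 6 h (adjusted p = 3.59e-07), provided that the transgene stands in for the tagged protein, which was not tested. An equal net rise under dTAG-13 in any line was excluded by the difference from the SETD2-dTAG line at 6 h (adjusted p = 3.23e-07), but a rise from the compound hidden there by loss of SETD2 stays open (median -0.10, adjusted p = 0.0549). Loss of the tagged NSD1 added to an effect of the compound may give both, which no group separates because no untagged line was treated, and the SETD2-dTAG line may differ in batch.

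By interaction tests in edgeR, 12 genes differed at 6 h between the line without transgene and wild-type rescue, and 2 against N1751Q. Batch and transgene cannot be separated there. Between the NSD1-dTAG and SETD2-dTAG lines 26 genes differed at 6 h and 18 at 24 h. Lists that differed by limma camera in the interaction were ribosomal proteins, with a median difference of -0.28 for N1751Q minus wild-type at 6 h (adjusted p = 5.40e-09, and 0.935 with an estimated correlation). For the line without transgene minus wild-type it was -0.23 at 6 h (0.00172, and 0.823) and 0.29 at 1 h (1.07e-06, and 0.61), and minus N1751Q 0.20 at 1 h (0.0205, and 0.956).

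For NSD1-dTAG minus SETD2-dTAG at 6 h the median difference was 0.39 for stress response genes (19 of 22 above 0), 0.24 for cholesterol biosynthesis (camera adjusted p = 0.0017, and 0.0206 with an estimated correlation), 0.27 for nucleolar factors (0.0225, and 0.0628) and -0.21 for ribosomal proteins (2.90e-05, and 0.58). At 24 h it was -1.06 for bivalent regulators, 0.25 for LIF/STAT3 targets (0.00387, and 0.0482), 0.21 for stress response genes (0.00635, and 0.0482), 0.14 for core pluripotency (0.00593, and 0.0862), 0.17 for naive pluripotency (0.0218, and 0.0693), 0.16 for BMP and TGF-beta/Nodal targets (0.0397, and 0.242) and 0.16 for ribosomal proteins (2.23e-04, and 0.435).

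Over other splits of the libraries, drawn within each contrast, chance was excluded for 2 interactions: the 6 h difference between NSD1-dTAG and SETD2-dTAG lines gave 26 genes against at most 14 in the other splits and 1 of 50 as large, and the 24 h difference 18 against 5, with 1 of 50. For the line without transgene, 4 of 50 splits gave at least the 12 genes of the difference from wild-type at 6 h (highest other 62) and 5 of 50 the 2 genes of the difference from N1751Q (highest other 24), so chance was not excluded. The other 4 interactions had 0 genes, which all 50 splits reach (highest other 1 and 28 for N1751Q minus wild-type at 6 h and 1 h, 28 and 1 for the line without transgene minus wild-type and minus N1751Q at 1 h).

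For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split and the highest other gave, on labelled reads, 60 and 0 genes at 6 h and 7 and 1 at 24 h in the NSD1-dTAG line, 81 and 1 and 12 and 0 in the SETD2-dTAG line, 9 and 1 at 6 h with wild-type NSD1, 186 and 0 and 21 and 0 between rescue lines at 0 h in batches 3 and 4, and 134 and 0 and 10 and 0 for 24 h against 6 h in the NSD1-dTAG and SETD2-dTAG lines, in each case with 1 of 10 as large. On all reads they gave 153 and 0, 62 and 15, 278 and 49, 75 and 0, and 2 and 0, again with 1 of 10. Where the real count was 0, all 10 were as large, and the highest other was 70 at 1 h without transgene, 15 at 1 h with wild-type NSD1 and 0 at 6 h and 1 h with N1751Q on labelled reads, and 1669, 118, 0 and 0 on all reads. The split of 1669 genes set 1 h replicate 1 and 0 h replicates 2 and 3 against the others, and that of 118 set 0 h replicate 1 and 1 h replicates 1 and 2, so these libraries held a structure other than the treatment, whose source was not tested.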

How the results depend on the processing

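Tests chosen only after the results were seen are those with ERCC scaling, with the labelling or T content trend removed, with genes of equal counted length, of lists on all reads, and the omission of N1751Q 6 h replicate 3 for its spike-in share. That omission left the edgeR counts of labelled reads in its 3 comparisons as they were and the difference in labelled share at -1.48 points. Leaving out 1 library kept a named gene's call in 527 cases and lost it in 421, with no change of sign. DESeq2 kept 112 and lost 2 of fewer cases than all-read scaling, which kept 107, lost 23 and turned 2. ERCC scaling kept 25, lost 56 and turned 1. The joint fit kept 17 and lost 63, and labelling trend removal kept 43 and lost 39. Depth and the spread between libraries limit what was callable: on simulated counts 2% of genes changed 1.5-fold were recovered at 1 h in the NSD1-dTAG line (edgeR biological coefficient of variation 34.5%), 14% at 6 h (23.5%) and 17% at 6 h with wild-type NSD1 (15.9%). The choice of 1 interval per gene was not run, since the tables had 1 line per gene. Except where libraries were left out, the cause of a change was not tested.

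With all-read scaling, genes past the threshold on labelled reads numbered 222, 5192 and 1778 at 1, 6 and 24 h in the NSD1-dTAG line, 182 at 6 h in the SETD2-dTAG line, 590 and 42 at 6 h and 131 at 1 h in rescue lines (42 with N1751Q, 590 and 131 with wild-type NSD1). They were 1022 and 1467 for the 6 h difference of the line without transgene from wild-type and N1751Q, 2274 and 892 for the 6 h and 24 h difference between degron lines, 671 between rescue lines at 0 h in batch 3, and 1491 and 226 for 24 h against 6 h in the NSD1-dTAG and SETD2-dTAG lines. At 6 h in the NSD1-dTAG line this scaling, which keeps the lower labelling, put Hsp90b1 at -0.035 and Suz12 at -0.29. ERCC scaling put Suz12 at -0.093, and since the median gene was at -0.76 and -0.56, both genes stayed above the bulk. It called 3417 and 1895 at 6 and 24 h in that line, 0 and 1 in the SETD2-dTAG line, 0 and 1 at 6 h with wild-type and N1751Q, and 231 at 1 h with N1751Q.

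DESeq2 called 139 and 34 at 6 and 24 h in the NSD1-dTAG line, 201 and 69 in the SETD2-dTAG line, 21 and 12 at 6 and 1 h with wild-type NSD1 and 1 at 1 h with N1751Q. For differences it called 58 and 1 (no transgene minus wild-type, 6 and 1 h), 160 and 60 (NSD1-dTAG minus SETD2-dTAG, 6 and 24 h), 49 (rescue lines at 0 h, batch 4), and 231 and 50 (24 h against 6 h in the NSD1-dTAG and SETD2-dTAG lines). On all reads it called 1, 404 and 200 at 1, 6 and 24 h in the NSD1-dTAG line, 484 and 152 in the SETD2-dTAG line, and 22 and 2 at 6 and 1 h with wild-type NSD1. Without a filter the counts were 13, 20, 22, 3 and 4 on labelled reads (NSD1-dTAG 24 h, SETD2-dTAG 24 h, wild-type 6 h, N1751Q 6 h, wild-type 1 h), and 3, 517 and 261 (NSD1-dTAG 1, 6 and 24 h), 585 and 146 (SETD2-dTAG 6 and 24 h) and 34 and 23 (wild-type 6 and 1 h) on all reads. The stricter filter gave 11 at 24 h in the NSD1-dTAG line. The joint fit of 48 libraries gave 11, 22 and 0 at 1, 6 and 24 h in the NSD1-dTAG line, 5 and 7 in the SETD2-dTAG line, 1 and 53 at 6 and 1 h with wild-type NSD1 and 1 at 1 h with N1751Q. A fit of only the 2 groups compared gave 133 at 6 h in the NSD1-dTAG line, 31 and 36 in the SETD2-dTAG line, and 0 and 22 at 6 h with wild-type NSD1 and N1751Q. With the labelling trend removed 2 were called at 24 h in the NSD1-dTAG line.

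Replicate numbers did not pair the libraries: on labelled reads 0 of 9, 3, 18, 18 and 9 same-number pairs in batches 1 to 4 and the SETD2-dTAG line had a correlation of deviations over 0.1, and 3 of 9, 0 of 3, 1 of 18, 2 of 18 and 0 of 9 on all reads. With the replicate block, the counts that moved were 20 (no transgene minus wild-type, 6 h), 0 (minus N1751Q, 6 h), 45 (NSD1-dTAG minus SETD2-dTAG, 6 h), 24 and 8 (rescue lines at 0 h, batches 3 and 4) on labelled reads, and 275 (NSD1-dTAG 6 h), 149 and 45 (SETD2-dTAG 6 and 24 h) and 7 (wild-type 6 h) on all reads.

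With an estimated correlation, the number of passing gene lists went from 2, 10 and 3 to 0, 1 and 1 at 1, 6 and 24 h in the NSD1-dTAG line, from 11 and 5 to 6 and 0 in the SETD2-dTAG line, and to 1, 1, 1 and 2 from 7, 4, 3 and 4 in rescue lines (wild-type and N1751Q at 6 h, then at 1 h). All-read scaling gave 11, 17 and 9 in the NSD1-dTAG line, 3 at 24 h in the SETD2-dTAG line, and 7, 5 and 10 (N1751Q 6 h, wild-type 1 h, N1751Q 1 h). The trend removed gave 6 and 3 in the SETD2-dTAG line and 3 and 2 at 6 h in rescue lines, and all reads 6 at 24 h in the NSD1-dTAG line and 5 and 2 in the SETD2-dTAG line. For the response of NSD1-dTAG 6 h genes, an estimated correlation gave adjusted p of 0.164 and 0.143 at 24 h in the SETD2-dTAG line (higher and lower genes), 0.165 for both at 6 h with wild-type NSD1, 0.0605 and 0.0777 at 1 h with it, and 0.156 for both at 1 h with N1751Q. All-read scaling put the higher genes at -0.49 (NSD1-dTAG 1 h), -0.15 (SETD2-dTAG 6 h), 0.065 (SETD2-dTAG 24 h), -0.24 (wild-type 6 h), -0.066 (N1751Q 6 h) and -0.24 (N1751Q 1 h), and the lower at -0.52 (NSD1-dTAG 1 h) and -0.057 (SETD2-dTAG 24 h). With the trend removed the lower genes had 0.047 (SETD2-dTAG 24 h), -0.053 (wild-type 6 h), -0.034 (wild-type 1 h) and -0.092 (N1751Q 1 h), and these calls ended (adjusted p = 0.278, 0.0555, 0.0843 and 0.110).

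Leaving out 1 library at a time gave, on labelled reads, 0, 13 to 52 and 0 to 11 genes at 1, 6 and 24 h in the NSD1-dTAG line, 17 to 174 and 4 to 12 in the SETD2-dTAG line, 0 to 14 and 0 to 4 at 6 and 1 h with wild-type NSD1, and 0 to 1 and 0 with N1751Q. Differences gave 0 to 1 and 0 (N1751Q minus wild-type, 6 and 1 h), 2 to 30 and 0 to 3 (no transgene minus wild-type), 0 to 2 and 0 (minus N1751Q), 8 to 95 and 10 to 21 (NSD1-dTAG minus SETD2-dTAG, 6 and 24 h), 91 to 125 and 8 to 27 (rescue lines at 0 h, batches 3 and 4), and 36 to 182 and 3 to 83 (24 h against 6 h, NSD1-dTAG and SETD2-dTAG). All reads gave 0, 32 to 205 and 14 to 123 in the NSD1-dTAG line, 11 to 1258 and 22 to 49 in the SETD2-dTAG line, 0 to 12 and 0 to 1 at 6 and 1 h with wild-type NSD1 and 0 with N1751Q. The difference in labelled share, in points, ran from -2.76 to -2.33, -4.76 to -4.73 and -3.11 to -2.86 in the NSD1-dTAG line, -0.991 to -0.83 and 0.257 to 0.572 in the SETD2-dTAG line, -1.7 to -1.35 and -1.37 to -1.21 at 6 and 1 h with wild-type NSD1, and -1.59 to -0.982 and -1.74 to -1.53 with N1751Q.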

Other observations

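The genes and values of this part were chosen only after the results were seen, and no explanation was tested for them.

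Some all-read changes have not been described. At 6 h in the NSD1-dTAG line Sohlh2, a germ cell transcription factor, was higher (log2 fold change 1.00), as were Kirrel2 (1.21) and Cd37 (1.51), and Sfrp1, a secreted Wnt inhibitor, was lower (-0.74). At 24 h Sohlh2 was also higher (1.01), with Rpe, of the pentose phosphate pathway (0.75), while the homeobox genes Hoxa7 (-1.83) and Cdx1 (-0.55) and the cyclin gene Ccnd2 (-0.64) were lower, and Msc, higher in new RNA at 24 h in the SETD2-dTAG line, was lower (-0.71). In the SETD2-dTAG line at 6 h Id1 (0.55) and Fdps, of sterol synthesis (0.52), were higher while Id3 (-0.56) and Pfkl, of glycolysis (-0.57), were lower. At 24 h in that line Bmp4 was higher (0.59) and Mid1 (-1.08) and the Mediator gene Med1 (-0.52) lower. All these passed edgeR over all genes in groups of 3 libraries.

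Cholesterol biosynthesis genes were also higher in all reads at 1 h with N1751Q, with a median of 0.15 and 22 of 24 above 0 (limma camera adjusted p = 2.05e-07, and adjusted p = 0.00575 with an estimated correlation), and at 1 h and 6 h without transgene (0.15 and 0.13, adjusted p = 0.00546 and 5.21e-04, and 0.439 and 0.0812 with an estimated correlation). Stress response genes in all reads had a median of 0.14 at 6 h with wild-type NSD1 (adjusted p = 1.19e-06, and 0.00807 with an estimated correlation), 0.16 at 6 h with N1751Q (1.04e-09, and 0.0022), 0.15 at 1 h with wild-type NSD1 (5.94e-04, and 0.144) and 0.13 at 1 h with N1751Q (1.48e-05, and 0.0262).

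A few genes of the difference between degron lines rest on low counts or on intervals that differ between tables, so only their labelled reads per library at 6 h and 0 h in the SETD2-dTAG line are given. They were 2, 3 and 0 against 11, 4 and 26 for Hsd17b7, 3, 2 and 7 against 13, 19 and 29 for Nip7, and 6, 8 and 4 against 0, 1 and 0 for Ube2c. Spike-in reads were 1.29% to 6.61% of all reads and lower in all treated than in all control libraries in 2 comparisons, 4.57% against 5.22% at 6 h in the NSD1-dTAG line and 4.88% against 6.3% at 1 h with wild-type NSD1 (exact permutation p = 0.1, the smallest possible). In the N1751Q line, 6 h replicate 3 had 3.78%.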
